A study of Homo sapiens with 9 samples.

How the data were processed

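RNA was measured in 9 libraries of LNCaP, an established human prostate cancer cell line grown in RPMI medium with serum. Cells had received 100 nM of a non-targeting siRNA (siCont) or 1 of 2 siRNAs against SETDB1 (siSETDB1-1 and siSETDB1-2) for 4 days, with 3 libraries in each of the 3 groups. Total RNA was made into libraries with a kit of the NEBNext Ultra RNA series, per the labels' protocols; that kit does not mark the strand of a transcript. The labels did not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

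The authors deposited a table of expected counts per gene, which are estimates that need not be whole numbers. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.6.1d, RSEM 1.3.2 and the build GRCh38 were used, with no settings given. The gene annotation release and the strand setting of the counting were not given in the sources used here. The table held 57905 genes, of which 26675 had a count in at least 1 library, and 4.23% of its values were not whole. All 9 count columns matched a labelled sample by name. Each expected count was rounded to a whole number before testing.

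The gene positions in the table were not those of GRCh38: only 365 of the 52338 gene identifiers shared with GENCODE release 29 had the same start. Coordinates given here were therefore taken from GENCODE 29 (GRCh38) by Ensembl identifier, never from the table. Identifiers in GENCODE 29 held 98.4% of the counts. Gene symbols came from a table of current names, which gave a symbol for 39538 identifiers; 33567 had a symbol in the deposited table, and 27 of those had been turned into dates by a spreadsheet. Genes on unplaced scaffolds took 0.777% of the counts.

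Total counts ranged from 8481542 to 14230900 per library. Genes were kept by the filterByExpr function (minimum count 10, minimum total 15), which left 14225 genes and 99.9% of the counts of each library. Counts were scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with all 9 libraries in a single fit that shared an estimate of the spread. The common dispersion was 0.00356, a biological coefficient of variation of 5.97%, with 6 residual degrees of freedom. Contrasts were siSETDB1-1 against siCont, siSETDB1-2 against siCont, the mean of both siRNAs against siCont, and siSETDB1-2 against siSETDB1-1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and "edgeR adjusted p" refers to that test throughout. CPM values are counts scaled to a common library size with TMM, given as mean ± SD of 3 libraries. Errors of log2 fold changes are approximate standard errors, the absolute log2 fold change divided by the square root of its F statistic. The 95% interval of the SETDB1 difference used such an error with a t quantile of 6 degrees of freedom. All intervals and errors rest on counts without molecular identifiers.

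Before the data were examined, the groups, tests, alternatives, 29 gene lists and the rule for the genes named were fixed. That rule took SETDB1 and RHOB; the 12 higher and 12 lower genes of largest mean change among those called in the same direction with both siRNAs; up to 4 members of each list with the smallest p in the mean contrast; and the 6 largest changes each way between the siRNAs. All but SETDB1 and RHOB had to have a symbol and a mean log2 CPM of at least 2, or at least 0 for list members. Genes outside this rule are said to have been chosen after their values were seen.

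The lists covered H3K9 methylation machinery, epithelial and mesenchymal genes, androgen response, type I interferon response, antigen presentation, NF-kB and inflammatory response, p53 targets, G2/M and DNA replication genes, and the integrated stress response. Further lists covered cholesterol and fatty acid synthesis, neuroendocrine and germline genes, endogenous retrovirus-derived genes, imprinted genes, ZNF genes, clustered protocadherins, replication-dependent histones, ribosomal proteins, mitochondrially encoded mRNAs and nuclear oxidative phosphorylation genes. Markers of basal prostate epithelium, fibroblasts and smooth muscle, endothelium and immune cells served for other cell types. Another 2 of the fixed lists, and some genes that the rule picked, are not reported here. Of the 1196 tested genes in any list, 13 were in more than 1.

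Lists with at least 3 tested members (27 of 29) were compared with all other genes by camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists, and repeated with a correlation estimated for each list. "Camera adjusted p" refers to the preset correlation. Member counts were also adjusted over the list alone. A hypoxia list and a scan of heptamers in annotated 3' UTRs were added after the data had been seen. The scan regressed the log2 fold change on the presence of each 7-base word in the 3' UTR, with UTR length and GC content in the model, over 11906 genes.

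In a chi-square test over genes, replicate libraries differed by 2.27 to 6.63 times sampling noise per degree of freedom, so no library looked like a copy of another. The tests were checked on simulated counts with 200 changed genes, as many up as down. At 1.5-fold, 64.6% were recovered for siSETDB1-1 (13879 genes), 76.3% for siSETDB1-2 (13858 genes) and 62.9% for both siRNAs in the same direction (13867 genes); at 2-fold the shares were 75.0%, 82.5% and 69.4%. False calls made up 4.90%, 6.10% and 1.53% of the calls. In the data 53.1% (siSETDB1-1) and 43.5% (siSETDB1-2) of the genes tested were called. The simulated shares thus hold for a far sparser change, and scaling was not checked with so many genes changed. In the list test, the shifted list was called and 0 of the others. All 3 shifts simulated for the UTR scan were recovered.

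Alternatives were DESeq2 size factors, total counts, other filters, the Wald test of DESeq2 1.42.0, limma-voom, a 2-fold minimum, only the groups compared, the replicate number as a block, and each library left out. Other scalings moved the median log2 fold change of all genes to between -0.054 and 0.0032. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the sequence scan and the plots.

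Without strand, reads of a gene and of an overlapping or antisense partner cannot be told apart: exons of 54 of the 138 named genes in GENCODE 29 overlap another gene, 38 of them on the other strand. Over 50% of the exon bases were overlapped in 6 named genes, among them CD68 (100%), RPL10 (61.25%) and ERVK3-1 (59.63%). Counts of near-identical copies, such as pseudogenes, histones, MAGE genes, ribosomal proteins and protocadherins with shared exons, are also uncertain. There a read can come from any of the genes that share the sequence.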

Results

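LNCaP cells, a line from human prostate cancer that depends on androgen signalling, were transfected with siRNAs against SETDB1, a histone H3K9 methyltransferase, to ask which genes respond to its loss and whether RHOB, which encodes a small GTPase, is among them. RNA was sequenced from 3 libraries with the control siRNA, 3 with siSETDB1-1 and 3 with siSETDB1-2. Total counts were 12485200, 9553833 and 11697154 for siCont, 8656696, 8481542 and 9926915 for siSETDB1-1, and 12775059, 13099733 and 14230900 for siSETDB1-2. The mean depth was thus lowest with siSETDB1-1. The third siSETDB1-1 library stood apart in its share of cytoplasmic rRNA (1.54% of counts, against 0.561% to 0.830% in the other libraries). In a principal component analysis, component 1 (43.9% of the variance) separated siSETDB1-1 from the remaining libraries and component 2 (23.3%) separated siSETDB1-2 from siCont. All values below are over n = 3 libraries per group.

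SETDB1 RNA (ENSG00000143379, chromosome 1, 150926263 to 150964744, plus strand, GRCh38) was lower in every library with either siRNA. Its counts were 697, 484 and 606 with siCont, 49, 70 and 73 with siSETDB1-1, and 94, 76 and 79 with siSETDB1-2. The level was 51.9 ± 2.47 CPM in control libraries, 7.07 ± 1.3 CPM with siSETDB1-1 (13.6% of control; log2 fold change -2.88 ± 0.12) and 6.38 ± 0.98 CPM with siSETDB1-2 (12.2%; -3.03 ± 0.12), with edgeR adjusted p = 2.25e-14 and 1.27e-14. The depth of loss did not differ detectably between the siRNAs (-0.15 ± 0.16, edgeR adjusted p = 0.431), with a 95% interval of -0.54 to 0.23. Exons of CERS2 on the other strand overlap 8.37% of the SETDB1 exon bases, and reads there cannot be assigned without strand.

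RHOB, which encodes a small GTPase found on endosomes and is the gene named in the title of the series, was higher with both siRNAs. It rose 2.10-fold with siSETDB1-1 (115.7 ± 4.68 to 243 ± 7.78 CPM; log2 fold change 1.07 ± 0.047, edgeR adjusted p = 3.22e-14) and 2.55-fold with siSETDB1-2 (295 ± 9.07 CPM; 1.35 ± 0.046, edgeR adjusted p = 1.42e-15). Counts were 1426, 1106 and 1433 with siCont, 2137, 2002 and 2460 with siSETDB1-1, and 3771, 3821 and 3948 with siSETDB1-2, so all 6 knockdown libraries lay above all controls. The rise was larger with siSETDB1-2 by 0.28 ± 0.044 (edgeR adjusted p = 1.57e-05). RHOB (ENSG00000143878) is a gene of 1 exon on chromosome 2, 20447074 to 20449445, plus strand, and its exon overlapped no other annotated gene. Its 3' UTR of 1389 bases holds 1 copy of the heptamer GACAGTA (20448965 to 20448971), and the 886 genes with that heptamer were higher by 0.15 ± 0.018 (mean of both siRNAs) than genes without it.

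**Figure D1:**
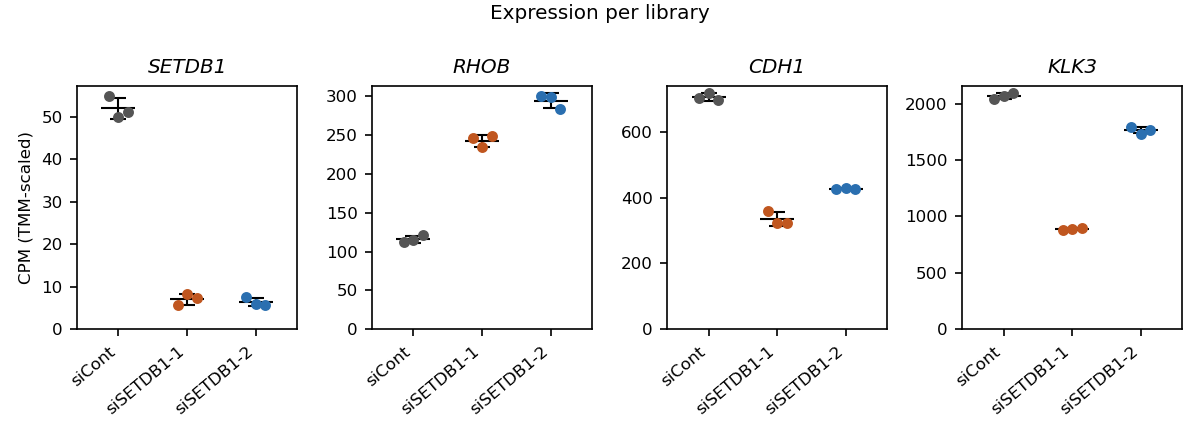
TMM-scaled CPM (vertical axis, from 0) of SETDB1, RHOB, CDH1 and KLK3 in each library, by group (horizontal axis); points are libraries, and bars the mean ± SD of 3. SETDB1 fell to 7.07 and 6.38 CPM and RHOB rose to 243 and 295 CPM, while KLK3 was lower with siSETDB1-1 than with siSETDB1-2.

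The genes that rose most with both siRNAs included fibrillar collagens, a protocadherin and a Notch ligand. The fibrillar collagen genes COL5A2 (log2 fold change 4.03 ± 0.15 with siSETDB1-1 and 2.95 ± 0.16 with siSETDB1-2) and COL3A1 (3.06 ± 0.26 and 2.51 ± 0.26) lie next to each other on chromosome 2, at 189031896 to 189225312 and 188974320 to 189012746. BASP1, a membrane-bound protein first described in neurons, rose by 3.17 ± 0.31 and 4.56 ± 0.27, and the protocadherin PCDH11X by 3.76 ± 0.33 and 2.73 ± 0.34. JAG1, a Notch ligand, rose by 2.42 ± 0.10 and 1.87 ± 0.10, the transcription factor SOX8 by 2.78 ± 0.17 and 1.53 ± 0.17, and GPC2, a cell-surface glypican, by 2.94 ± 0.27 and 1.47 ± 0.29. DHRS2, a short-chain dehydrogenase, rose by 4.72 ± 0.12 with siSETDB1-1 but by 1.38 ± 0.15 with siSETDB1-2. The remaining genes of this rank were NUDT19-DT (2.97 and 2.55), ZNF812P (2.03 and 2.31), GUSBP1 (2.53 and 2.29) and FAR2P2 (3.04 and 1.78); these are a divergent transcript and pseudogenes, whose reads can come from their relatives. The least certain of these changes was that of GPC2 with siSETDB1-2 (edgeR adjusted p = 0.000256). Several of these genes had few counts in the control libraries, so the size of their fold changes is uncertain. Control counts were 5, 3 and 9 for BASP1, 16, 5 and 10 for PCDH11X, and 11, 10 and 17 for COL3A1. They were 11, 7 and 13 for NUDT19-DT and 20, 7 and 20 for GPC2, but 121, 110 and 166 for JAG1.

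Apart from SETDB1 itself, the genes that fell most with both siRNAs include enzymes and transporters of glycolysis and collagen modification. PLOD2, a lysyl hydroxylase of collagen (chromosome 3, 146069440 to 146163653), fell to 10.7% and 11.1% of control (-3.23 ± 0.18 and -3.17 ± 0.17). SLC16A3, the lactate exporter MCT4, changed by -2.63 ± 0.15 and -2.10 ± 0.14, PFKFB4, a regulator of glycolytic flux, by -2.43 ± 0.15 and -1.60 ± 0.13, and the secreted hormone STC1 by -3.01 ± 0.25 and -2.28 ± 0.22. NDUFA4L2, a mitochondrial protein, fell further with siSETDB1-2 (-1.70 ± 0.16 and -3.56 ± 0.18). UGT2B28, which glucuronidates steroids, changed by -2.36 ± 0.13 and -2.28 ± 0.12, SLC7A2, a cationic amino acid transporter, by -3.07 ± 0.16 and -1.62 ± 0.13, and BIRC3, an inhibitor of apoptosis, by -3.01 ± 0.25 and -1.79 ± 0.21. GJB1 (-2.97 and -0.72) and CRYBG1 (-2.67 and -1.02) fell mainly with siSETDB1-1, and CLDND1 (chromosome 3, 98497912 to 98523066) mainly with siSETDB1-2, to 4.45% of control (-0.25 ± 0.093 and -4.49 ± 0.14). The largest edgeR adjusted p among these values was 0.0266, for CLDND1 with siSETDB1-1.

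In all, 2916 of 14225 genes (20.5%) were called in the same direction with both siRNAs, 1502 higher and 1414 lower; 142 and 135 of these changed at least 2-fold with each. Independent lists of the same sizes would share 857 and 785 genes. A further 476 genes were higher with siSETDB1-1 and lower with siSETDB1-2, and 732 the reverse, against 787 and 855 for independent lists, and all of these were also called in the contrast between the siRNAs. Across genes, which are not independent replicates, the fold changes of the siRNAs had a Pearson r of 0.408. Unchanged groups simulated 50 times against the same 3 controls gave 0.491 (0.453 to 0.535), and the same-sign share was 61.9% against 66.4% simulated. The covariance was 0.175 against 0.0309 simulated, a difference of 0.144. The 3 controls could not be split into parts of at least 2 libraries, so part of the excess overlap may come from the shared controls. Without the third siSETDB1-1 library, 3035 genes were called in the same direction. With the mean of both siRNAs against siCont, 6684 genes were called, 3256 higher and 3428 lower.

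**Figure D2:**
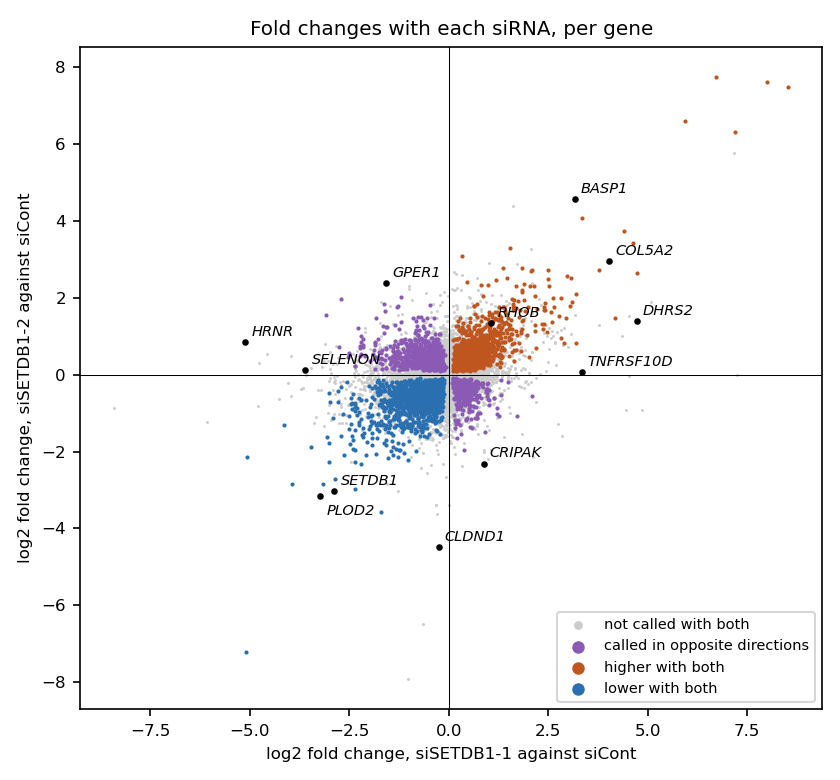
Log2 fold change against siCont with siSETDB1-1 (horizontal) and siSETDB1-2 (vertical) for each of the 14225 genes tested; colours mark genes called higher with both (1502), lower with both (1414) or in opposite directions, and black points are named genes. SETDB1 and PLOD2 lie low on both axes, BASP1, COL5A2 and RHOB high on both, and HRNR, GPER1 and CLDND1 far from the diagonal.

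Genes of cell division fell with both siRNAs. All 42 tested G2/M genes were lower with each siRNA, with the same numbers adjusted over the list alone; the median of the mean contrast was -0.66 (camera adjusted p = 1.58e-18, and 0.000969 with an estimated correlation). FOXM1, which drives G2/M transcription, changed by -1.63 ± 0.064 and -0.95 ± 0.059, the spindle checkpoint kinase BUB1 by -0.95 ± 0.079 and -1.39 ± 0.078, and HMMR by -0.76 ± 0.065 and -1.13 ± 0.064. Of 45 genes of DNA replication and G1/S, 35 fell, 1 rose and 9 were not called in the mean contrast (35 and 1 adjusted over the list alone), and 26 fell with both siRNAs (median -0.42, camera adjusted p = 2.19e-10). Thymidine kinase TK1 changed by -1.47 ± 0.061 and -0.47 ± 0.056, TYMS by -1.10 and -0.73, and the ribonucleotide reductase subunits RRM1 by -0.57 and -0.67 and RRM2 by -0.75 and -0.40. Exons of ENOSF1 and another gene overlap 64.6% of the exon bases of TYMS. Genes of the replication-dependent histone list went the other way: 17 of 35 rose, 0 fell and 18 were not called, with the same numbers adjusted over the list alone (median 0.55, camera adjusted p = 0.000229). The list was set by gene name, so it cannot tell whether the histone mRNA made for DNA replication rose. Without the first control library the median of log2 CPM values fell from 0.54 to 0.24 and the list was still called (camera adjusted p = 0.000655). Examples were H2BC21 (0.77 ± 0.053 and 1.28 ± 0.051), H2AC6 (0.97 and 1.31) and H2BC5 (1.57 and 1.41). With siSETDB1-1 alone the histone call was lost with an estimated correlation (adjusted p = 0.153). Histone mRNAs took 0.0486 ± 0.0017% of counts with siCont, 0.0570 ± 0.0013% with siSETDB1-1 and 0.0912 ± 0.0009% with siSETDB1-2.

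Epithelial genes fell with siSETDB1-1, and mesenchymal genes were called as a group with siSETDB1-2 alone, a call lost with an estimated correlation (adjusted p = 0.24). In the direct test of the siRNAs the mesenchymal list did not differ detectably (camera adjusted p = 0.655). CDH1, the E-cadherin gene of adherens junctions, fell from 707 to 335 and 427 CPM (-1.08 ± 0.042 and -0.73 ± 0.041), and CLDN4, a tight junction claudin, changed by -1.32 ± 0.048 and -0.36 ± 0.045. KRT19 changed by -3.01 ± 0.18 and -0.47 ± 0.13, whereas PRSS8, an epithelial serine protease, was lower with siSETDB1-1 (-2.11 ± 0.075) and higher with siSETDB1-2 (0.48 ± 0.061). Of 38 epithelial genes, 29 fell and 2 rose with siSETDB1-1 (29 and 2 adjusted over the list alone; median -0.48, camera adjusted p = 4.23e-07), against 8 and 13 with siSETDB1-2 (8 and 14 adjusted over the list alone; median 0.035, camera adjusted p = 0.794). In the mean contrast 22 fell, 4 rose and 12 were not called (camera adjusted p = 0.0004). Among mesenchymal genes, CALD1 (0.96 ± 0.037 and 0.85 ± 0.036), COL6A1 (0.74 and 0.91) and FN1 (1.02 and 0.49) rose with both. For the mean of both siRNAs, 10 of 23 rose, 4 fell and 9 were not called, with the same numbers adjusted over the list alone (median 0.14, camera adjusted p = 0.0497; adjusted p = 0.225 with an estimated correlation). Without the first siSETDB1-1 library the median of log2 CPM values fell to 0.055. The call of the mean contrast was lost with any library left out except the second control library, and with siSETDB1-1 alone (camera adjusted p = 0.254).

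Androgen-responsive genes fell with siSETDB1-1. KLK3, which encodes prostate-specific antigen, changed by -1.22 ± 0.033 with siSETDB1-1 and -0.23 ± 0.032 with siSETDB1-2, TMPRSS2 by -1.79 ± 0.043 and -0.13 ± 0.040, and NDRG1 by -2.42 ± 0.047 and -0.91 ± 0.041. Of 41 genes, 29 fell and 6 rose with siSETDB1-1, with the same numbers adjusted over the list alone (median -0.68, camera adjusted p = 4.23e-07), against 15 and 12 with siSETDB1-2, also the same over the list alone (median -0.015, mean 0.0032, camera adjusted p = 0.923). Averaged over the siRNAs, 24 fell, 7 rose and 10 were not called (camera adjusted p = 8.66e-05). Other lists hold 6 of the androgen genes, 3 of them lists of lipid synthesis.

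Fatty acid synthesis genes were lower with siSETDB1-1; in the direct test of the siRNAs the fatty acid and cholesterol calls were lost with an estimated correlation (adjusted p = 0.065 and 0.0561). Of 24 fatty acid genes, 16 fell and 1 rose with siSETDB1-1, with the same numbers adjusted over the list alone (median -0.67, camera adjusted p = 1.38e-06; adjusted p = 0.0519 with an estimated correlation), against 9 and 3 with siSETDB1-2 (median -0.018, camera adjusted p = 0.489). In the mean contrast 15 fell, 3 rose and 6 were not called (camera adjusted p = 8.66e-05; adjusted p = 0.087 with an estimated correlation). FASN, the fatty acid synthase, changed by -1.41 ± 0.046 and -0.64 ± 0.045, the desaturase genes SCD by -1.81 ± 0.041 and -0.20 ± 0.039, FADS1 by -2.25 and -0.98 and FADS2 by -1.84 and -0.34, and their regulator SREBF1 by -1.65 and -0.14. The cholesterol list was lower with siSETDB1-1, where 15 of 24 fell and 3 rose (16 and 3 adjusted over the list alone; median -0.30, camera adjusted p = 0.000516), but was not called in the mean contrast, where 13 fell, 3 rose and 8 were not called (camera adjusted p = 0.0589). With siSETDB1-2, 10 cholesterol genes rose and 7 fell (11 and 7 adjusted over the list alone, median 0.15, camera adjusted p = 0.687). INSIG1 (-0.76 and -0.94), EBP (-0.83 and -0.55) and FDPS (-0.27 and -0.53) fell with both siRNAs. Of the 24 genes, 6 were called lower with both and 7 in opposite directions.

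Type I interferon response genes fell with siSETDB1-1. OAS3, a sensor of double-stranded RNA, changed by -1.64 ± 0.12 and -1.31 ± 0.11, whereas STAT2, a transducer of the interferon signal, changed by -1.22 ± 0.15 with siSETDB1-1 and by -0.25 ± 0.13 with siSETDB1-2 (edgeR adjusted p = 0.139). With siSETDB1-1, 26 of 38 genes fell and 0 rose (27 and 0 adjusted over the list alone; median -0.84, camera adjusted p = 4.23e-07), against 4 and 3 with siSETDB1-2 (camera adjusted p = 0.489). For the mean of both siRNAs, 20 fell, 1 rose and 17 were not called (22 and 1 adjusted over the list alone; camera adjusted p = 0.000229). Of 22 antigen presentation genes, 10 fell, 0 rose and 12 were not called in the mean contrast, with the same numbers adjusted over the list alone (camera adjusted p = 0.00467; adjusted p = 0.235 with an estimated correlation). With siSETDB1-1, 17 fell and 0 rose (median -0.41, camera adjusted p = 9.65e-05, and 0.153 with an estimated correlation). With siSETDB1-2, 5 fell and 5 rose (median -0.023, camera adjusted p = 0.923). TAPBP, which loads peptide onto class I molecules, changed by -1.92 ± 0.070 and -0.57 ± 0.060 and HLA-DMA by -1.61 and -0.87. HLA-E (-0.78 ± 0.089 and -0.014 ± 0.080) and HLA-B (-0.73 ± 0.068 and 0.12 ± 0.062) were called with siSETDB1-1 alone. The inflammatory list was not called (1 of 13 rose, 5 fell and 7 were not called; 1 and 6 adjusted over the list alone; camera adjusted p = 0.0977), although NFKB1 rose (0.54 and 0.52) and NFKB2 (-0.31 and -0.81) and SOD2 (-0.49 and -0.27) fell.

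Targets of p53 rose with siSETDB1-1. CDKN1A, the inhibitor of cyclin-dependent kinases p21, rose by 1.75 ± 0.039 with siSETDB1-1 and had -0.093 ± 0.039 with siSETDB1-2 (edgeR adjusted p = 0.06). ZMAT3 rose by 2.45 ± 0.081 and had 0.10 ± 0.092 (edgeR adjusted p = 0.389). SESN1 (1.62 ± 0.074 and 1.67 ± 0.072) and TP53INP1 (1.45 ± 0.059 and 1.36 ± 0.058) rose with both. With siSETDB1-1, 27 of 33 rose and 0 fell (27 and 1 adjusted over the list alone; median 0.71, camera adjusted p = 1.68e-10), against 7 and 9 with siSETDB1-2 (median -0.046, camera adjusted p = 0.823). Averaged over the siRNAs, 24 rose, 3 fell and 6 were not called, with the same numbers adjusted over the list alone (camera adjusted p = 1.16e-05). Of 33 genes of the integrated stress and unfolded protein response, 14 fell, 5 rose and 14 were not called (15 and 5 adjusted over the list alone; median -0.11, camera adjusted p = 0.0497; adjusted p = 0.235 with an estimated correlation). EDEM1 (-0.92 and -1.35), MANF (-0.47 and -0.90), TRIB3 (-1.36 and -0.46) and PHGDH (-0.79 and -0.30) fell with both, and the list call was lost in 7 of the 9 settings that left out a library; without the third control library the median was -0.071.

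Clustered protocadherin genes rose with siSETDB1-2. With it 19 of 29 rose and 0 fell, with the same numbers adjusted over the list alone (median 1.10, camera adjusted p = 8.31e-06), against 6 and 4 with siSETDB1-1 (5 and 4 adjusted over the list alone; median 0.20, camera adjusted p = 0.693). In the mean contrast 15 rose, 2 fell and 12 were not called (16 and 2 adjusted over the list alone; camera adjusted p = 0.00183; adjusted p = 0.0863 with an estimated correlation). PCDHGA5 had 0.13 ± 0.25 with siSETDB1-1 and rose by 2.67 ± 0.19 with siSETDB1-2, PCDHB14 rose by 1.59 ± 0.29 and 1.96 ± 0.27, and PCDHGC3, which shares exons with the rest of its cluster, fell by 1.48 with siSETDB1-1. ZNF genes, many of which encode KRAB repressors of retroelements, rose with siSETDB1-1, where 163 of 457 rose and 32 fell (158 and 28 adjusted over the list alone; median 0.26, camera adjusted p = 3.51e-05), against 87 and 41 with siSETDB1-2 (74 and 27 adjusted over the list alone; median 0.088, camera adjusted p = 0.335). For the mean of both siRNAs, 128 rose, 32 fell and 297 were not called (126 and 32 adjusted over the list alone; median 0.16, camera adjusted p = 0.000369). Named members were ZNF737 (1.23 and 1.42), ZNF613 (0.91 and 1.24) and ZNF395 (-1.04 and -1.06).

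Lists of other silenced or chromatin genes were not called in the mean contrast. Of 17 imprinted genes, 7 rose, 3 fell and 7 were not called (7 and 4 adjusted over the list alone; camera adjusted p = 0.146). GRB10, an adaptor of growth factor receptors, rose by 2.42 ± 0.049 and 1.68 ± 0.049, PEG3 by 0.46 ± 0.056 and 2.40 ± 0.052 and NDN by 0.90 and 0.48. Of 18 germline genes, 7 rose, 3 fell and 8 were not called (8 and 3 adjusted over the list alone; camera adjusted p = 0.0942). MAGEA3 rose by 0.71 ± 0.055 and 0.24 ± 0.055, and its near-identical relatives MAGEA6 (0.80 and 0.13) and MAGEA12 (0.94 and 0.19) passed with siSETDB1-1 alone. With siSETDB1-2 the germline median was 0.12, its mean -0.036 and its test above 0. Among 6 retrovirus-derived genes 1 rose, 1 fell and 4 were not called, with the same numbers adjusted over the list alone (camera adjusted p = 0.611). ERVK3-1 had -0.11 ± 0.081 and 0.56 ± 0.074, and the siSETDB1-2 median (0.0039) and mean (-0.17) differed in sign. Of 25 genes of the H3K9 methylation machinery, 8 rose, 5 fell and 12 were not called (8 and 6 adjusted over the list alone; camera adjusted p = 0.754). KDM4A, a demethylase of H3K9 with 55.2% of its exon bases shared with other genes, rose by 1.20 ± 0.069 and 0.51 ± 0.070, EHMT1 rose by 0.47 and 0.40, and CBX5, the HP1 alpha gene, had -0.098 ± 0.057 with siSETDB1-1 and -0.78 ± 0.057 with siSETDB1-2. This list had a median of 0.019 and a mean of -0.0093 with siSETDB1-1, and -0.036 and 0.040 with siSETDB1-2.

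Mitochondrially encoded mRNAs rose with both siRNAs. Averaged over the siRNAs, 11 of 13 rose, 0 fell and 2 were not called, with the same numbers adjusted over the list alone (median 0.33, camera adjusted p = 0.000369; adjusted p = 0.303 with an estimated correlation). Examples, all subunits of respiratory complex I, were MT-ND6 (0.64 ± 0.036 and 0.34 ± 0.036), MT-ND3 (0.79 and 0.19) and MT-ND1 (0.43 and 0.37). Mitochondrial rRNA, in contrast, was 3.31 ± 0.093% of counts with siCont, 2.73 ± 0.13% with siSETDB1-1 and 4.49 ± 0.11% with siSETDB1-2. Of 83 ribosomal protein genes, 69 rose and 5 fell with siSETDB1-1 (70 and 5 adjusted over the list alone; median 0.21, camera adjusted p = 4.23e-07; adjusted p = 0.519 with an estimated correlation), against 12 and 20 with siSETDB1-2 (camera adjusted p = 0.794), where the median was 0 and the mean -0.066. In the mean contrast 47 rose, 6 fell and 30 were not called (48 and 8 adjusted over the list alone; median 0.099, camera adjusted p = 0.00183; adjusted p = 0.65 with an estimated correlation). These genes took 10.5% of counts in the third siSETDB1-1 library, which also had the largest share of cytoplasmic rRNA, and 9.40% and 9.55% in the other siSETDB1-1 libraries. Without the third, the median was 0.071 (camera adjusted p = 0.00715). RPL35A (0.54 and 0.17) rose and RPL10 (-0.23 and -0.26) fell with both, and RPS28 was lower with siSETDB1-2 (0.15 ± 0.043 and -1.40 ± 0.045). Nuclear oxidative phosphorylation genes were not called (14 of 74 rose, 16 fell and 44 were not called; 13 and 15 adjusted over the list alone; median 0.0089, mean -0.0080, camera adjusted p = 0.935). ATP5F1B, a subunit of ATP synthase, changed by -0.89 ± 0.034 with siSETDB1-1 and had 0.024 ± 0.033 with siSETDB1-2.

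Few markers of other cell types were expressed at a testable level. Of 15 basal prostate genes 5 were tested; all 5 fell with siSETDB1-1, also adjusted over the list alone (median -1.38, camera adjusted p = 0.0082; adjusted p = 0.0701 with an estimated correlation), against 2 lower and 2 higher with siSETDB1-2. The mean contrast was not called (3 fell, 1 rose and 1 was not called, also adjusted over the list alone; camera adjusted p = 0.146). ITGA6 changed by -1.58 ± 0.096 and -0.68 ± 0.084, DST by -1.51 and -0.38, and LAMA3 by -0.50 ± 0.073 and 0.83 ± 0.066. Of 5 tested fibroblast and smooth muscle genes, 3 of them also on the mesenchymal list, 2 rose, 0 fell and 3 were not called in the mean contrast (2 and 1 adjusted over the list alone; camera adjusted p = 0.298). ACTA2, with an antisense gene over 38.3% of its exon bases, was higher with siSETDB1-1 (1.72 ± 0.26) and lower with siSETDB1-2 (-1.07 ± 0.31). Of 6 neuroendocrine genes 2 rose, 2 fell and 2 were not called, with the same numbers adjusted over the list alone (camera adjusted p = 0.575). DDC, which makes dopamine and serotonin, rose by 2.58 ± 0.071 and 1.64 ± 0.072 and ENO2 changed by -0.71 and -1.59. With siSETDB1-2 the neuroendocrine median was 0.079 and its mean -0.0039. The endothelial genes EGFL7 (0.26 and 0.56) and VWF (-0.49 and -0.37, the latter with edgeR adjusted p = 0.0588) and the immune gene CD68 (-2.70 and -0.28) were the only tested members of their lists, too few for a list test. Other annotated genes overlap 100% of the exon bases of CD68, so its reads cannot be told apart from theirs.

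**Figure D3:**
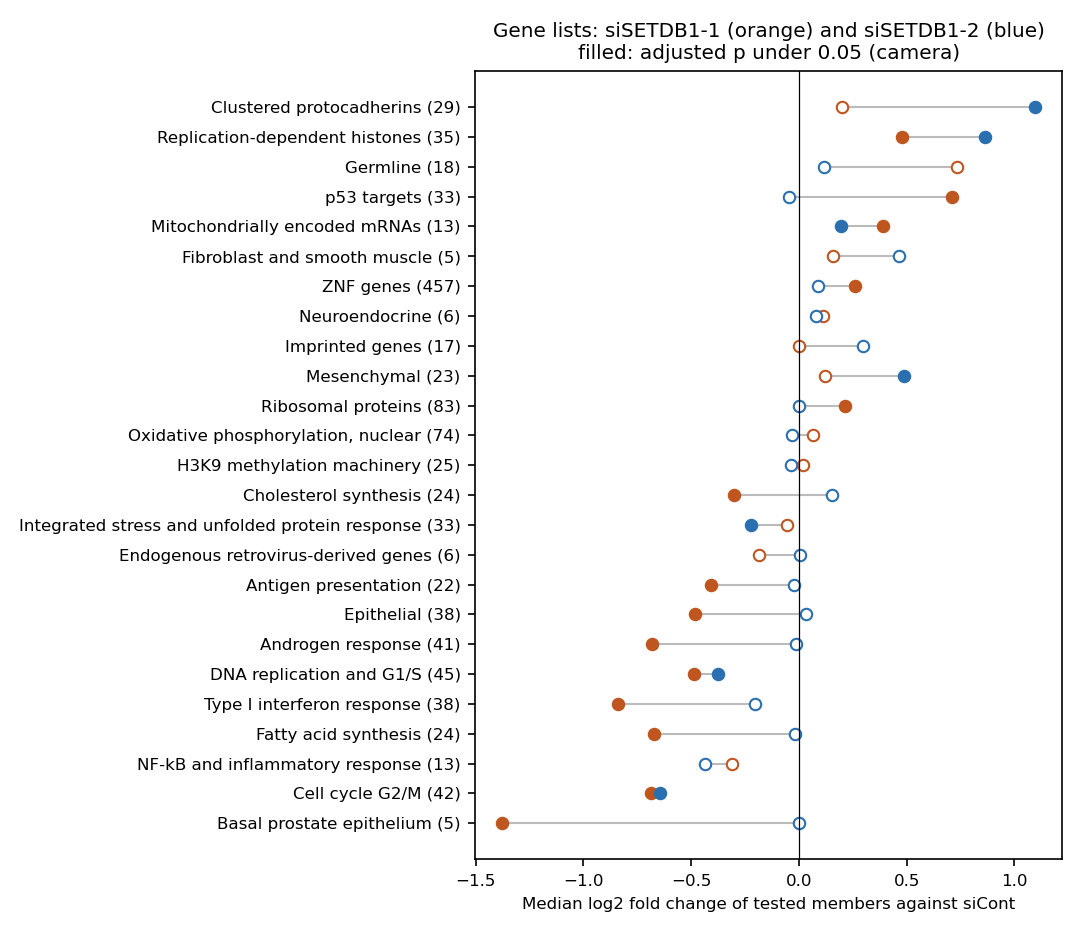
Median log2 fold change of the tested members of each gene list (horizontal axis; number of members in brackets) with siSETDB1-1 (orange) and siSETDB1-2 (blue) against siCont; filled points have a camera adjusted p under 0.05 and lines join the siRNAs. Of the 25 lists shown, G2/M, DNA replication, histone and mitochondrial mRNA lists are filled on the same side for both, though with an estimated correlation the mitochondrial calls (adjusted p = 0.396 and 0.736) and the siSETDB1-1 histone call (adjusted p = 0.153) were lost; p53 targets and androgen response are filled for siSETDB1-1 alone.

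With siSETDB1-1 against siCont, G2/M, androgen, interferon and epithelial genes were among the groups that fell, and p53 targets rose. Genes called numbered 7547 (53.1% of those tested), 3778 higher and 3769 lower, and of the 1513 that changed at least 2-fold 461 were higher and 1052 lower. SELENON, a selenoprotein of the endoplasmic reticulum, fell to 8.23% of control (-3.60 ± 0.077, edgeR adjusted p = 2.19e-19), and TNFRSF10D, a decoy receptor of TRAIL, rose by 3.34 ± 0.071. Of the 27 lists, 14 were called, and antigen presentation, fatty acid synthesis, histones, ribosomal proteins, mitochondrial mRNAs and basal genes lost the call with an estimated correlation (adjusted p = 0.153, 0.0519, 0.153, 0.519, 0.396 and 0.0701). Genes with the heptamer GCCACTG in the 3' UTR (2364 genes) were lower by 0.29 on the log2 scale (shift -0.29 ± 0.017), against -0.040 ± 0.013 with siSETDB1-2.

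With siSETDB1-2 against siCont, protocadherin and histone genes were higher and cell division genes lower. Genes called numbered 6189 (43.5%), 3226 higher and 2963 lower, and 398 each way changed at least 2-fold. The balance depended on scaling: with total counts, 2692 of 6218 called genes were higher. GPER1, a membrane receptor for estrogen, rose by 2.37 ± 0.16 and PEG3 by 2.40, and CRIPAK, an inhibitor of PAK1, changed by -2.31 ± 0.19. Of the 27 lists, 7 were called, and mesenchymal, stress response and mitochondrial mRNA genes lost the call with an estimated correlation (adjusted p = 0.24, 0.42 and 0.736). In this contrast 15 of 23 mesenchymal genes rose and 4 fell (15 and 5 adjusted over the list alone; median 0.49, camera adjusted p = 0.0294). Carriers of the heptamer CTGCTCA (1587 genes) were lower (shift -0.19 ± 0.015), against -0.014 ± 0.019 with siSETDB1-1.

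Compared directly, the siRNAs differed in single genes such as HRNR and in lists such as androgen response, interferon, epithelial and p53 genes. In this contrast 7611 genes were called, 3786 higher and 3825 lower with siSETDB1-2, and 1078 and 508 changed at least 2-fold. Genes higher with siSETDB1-2 included HRNR, an epidermal protein (difference 5.95 ± 0.33; -5.12 ± 0.36 with siSETDB1-1 and 0.84 ± 0.17 with siSETDB1-2), GPER1 (3.94 ± 0.20), SELENON (3.72 ± 0.076), SUSD2 (3.46 ± 0.15) and PLA2G7 (3.37 ± 0.28). Genes lower with siSETDB1-2 were CLDND1 (-4.24 ± 0.14), DHRS2 (-3.34 ± 0.10), TNFRSF10D (-3.28 ± 0.069), CRIPAK (-3.19 ± 0.18), MFSD3 (-2.40 ± 0.064) and SIPA1L2 (-2.39 ± 0.085). The androgen list differed by a median of 0.75 (29 of 41 higher with siSETDB1-2 and 6 lower, also adjusted over the list alone; camera adjusted p = 9.69e-08), epithelial genes by 0.44, interferon genes by 0.87 and p53 targets by -0.90 (25 of 33 lower; camera adjusted p = 1.17e-08). Antigen presentation (median 0.52), cholesterol (0.29), fatty acid (0.66), protocadherin (1.03) and basal genes (1.33) were also higher with siSETDB1-2, and ZNF (-0.21), ribosomal protein (-0.23) and nuclear oxidative phosphorylation genes (-0.13) lower; these calls were lost with an estimated correlation (adjusted p = 0.262, 0.0561, 0.065, 0.065, 0.065, 0.065, 0.608 and 0.706). SETDB1 did not differ detectably between the siRNAs. The G2/M list did not differ detectably (median -0.015, camera adjusted p = 0.872).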

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

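The genes and lists of the last paragraph were picked out because the siRNAs differed in them at an adjusted p under 0.05 when tested directly against each other, genes in edgeR and lists with camera. The splits of the libraries, and RHOB with 2 of the 3 scalings and with each library left out, were planned; the third scaling, the bounds set for RHOB, and the tests of the heptamers and the androgen genes were chosen after the results had been seen.

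Genes with certain heptamers in their 3' UTR were lower on average, with a different heptamer for each siRNA; of GCCACTG carriers 40.7% were called lower and 19.9% higher with siSETDB1-1 (26.4% and 30.9% of other genes), and of CTGCTCA carriers 33.8% and 18.5% with siSETDB1-2 (21.2% and 26.0%). GCCACTG had the lowest t with siSETDB1-1 (t = -17.21, largest t in either direction with shuffled values 4.44) and CTGCTCA with siSETDB1-2 (t = -13.17, shuffled 4.78). UTR length and GC content were in the model, which argues against those as the cause. Chosen on odd chromosomes alone, the same heptamers ranked first on the other chromosomes among heptamers with at least 50 carriers (shifts of -0.27 and -0.19, the weaker -0.1895). With 0, 1, 2 and 3 or more copies of GCCACT (the first 6 bases of GCCACTG), the median change with siSETDB1-1 was 0.056, -0.091, -0.16 and -0.24. These medians were not adjusted for UTR length or GC content, so longer UTRs may add to the trend. A candidate explanation is repression by each siRNA through matches to its seed, since the SETDB1 transcript holds GCCACTG across the junction of exons 8 and 9 and CTGCTCA in exons 9 and 18, but 21.6% of all heptamers occur in that transcript and the siRNA sequences were not given in the sources used here. For 4315 genes, the 3' UTR of the single transcript scanned held none of the scanned hexamers. Of these, 948 (22.0%) were called in the same direction with both siRNAs and 355 (8.23%) in opposite directions. Among all 11906 genes with an annotated 3' UTR, which include these 4315, the shares were 22.7% and 9.78%. Genes without these hexamers may still hold other sites.

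Androgen response genes were lower with siSETDB1-1 than with siSETDB1-2 (median difference 0.75 over 41 genes). Deeper loss of SETDB1 RNA with siSETDB1-1 was set to need a difference of at least 0.585 (1.5-fold), and the upper 95% bound was 0.229, which argues against it at the level of RNA; SETDB1 protein was not measured. GCCACT in the members' own UTRs was argued against as the sole cause by the 23 members with an annotated 3' UTR and no GCCACT. Their median difference was 0.66 (quartiles 0.29 to 0.99), and 17 were lower with siSETDB1-1. Other sites are not excluded. Carriers of CCACTGA, CCACTGT and CCACTGC, which need not hold GCCACT, were also lower with siSETDB1-1 (t = -12.23, -7.84 and -7.59). Coding sequences of the members were not scanned. An indirect effect of siSETDB1-1 through other genes, apart from loss of SETDB1, was not tested and stays open.

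RHOB was higher with both siRNAs, by 1.07 and 1.35; scaling is argued against by a lowest value of 1.17 under 3 other scalings, and a single library by a lowest value of 1.19 with each library left out. The RHOB 3' UTR carries GACAGTA, the heptamer with the highest t with both siRNAs (6.34 and 7.80). Other heptamers had larger shifts, such as AGACGTA (0.28 and 0.23, against 0.15 and 0.14 for GACAGTA). A seed site of the control siRNA could give this pattern, since both comparisons share that siRNA. GACAGTA also occurs in the SETDB1 transcript, so presence there does not single out seeds of the SETDB1 siRNAs. Of 885 other carriers 2.6% rose as much as RHOB, against 1.23% of genes without the heptamer, and on chromosomes other than the odd ones GACAGTA ranked 1 with both siRNAs, but neither is an independent check, since GACAGTA was chosen on these same genes; the heptamer chosen on odd chromosomes, ACAGTAT, which shares ACAGTA with it, ranked 239 and 4752 there. Relief from repression by SETDB1 and lost repression by the control siRNA cannot be told apart for RHOB, as no untreated cells were sequenced.

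For the number of genes called, splits of the 9 libraries into groups of the same sizes gave as many for the mean of both siRNAs in 1 of 100, the real split (6684, highest other 4991). A random grouping of these 9 libraries thus rarely gives such a count. Differences between cultures are not tested by the splits, since the replicates may not be separate cultures. For genes called in the same direction with both siRNAs, 2 of 100 splits gave as many (2916, highest other 3155). That share is under 0.05, but the split with 3155 took the 3 siSETDB1-1 libraries as the control against mixtures of siCont and siSETDB1-2. A large shared count thus also arises when the reference group itself stands apart, and the splits say nothing of a shared response to the siRNAs. For siSETDB1-1 against siCont (7547, highest other 0), siSETDB1-2 against siCont (6189, highest other 0) and the siRNAs against each other (7611, highest other 0), 10 splits, of which 1 gave as many, are too few for a share under 0.05.

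The direct comparison called 7611 genes. List medians, siSETDB1-2 minus siSETDB1-1, were 0.44 for epithelial, 0.75 for androgen response, 0.87 for interferon, 0.52 for antigen presentation, -0.90 for p53, 0.29 for cholesterol, 0.66 for fatty acid, -0.21 for ZNF, 1.03 for protocadherin, -0.23 for ribosomal protein, -0.13 for nuclear oxidative phosphorylation and 1.33 for basal genes. With an estimated correlation 8 of these 12 calls were lost: antigen presentation (adjusted p = 0.262), cholesterol (0.0561), fatty acid, ZNF, protocadherin and basal genes (0.065 each), ribosomal protein (0.608) and oxidative phosphorylation genes (0.706). Among genes changed in the same direction with both siRNAs, differences were 0.28 for RHOB, 1.39 for BASP1, -1.08 for COL5A2, -1.03 for PCDH11X, -3.34 for DHRS2, -0.55 for COL3A1, -1.26 for FAR2P2, -1.47 for GPC2, 0.28 for ZNF812P, -1.25 for SOX8 and -0.55 for JAG1. Among those lower with both they were 0.73 for STC1, -1.86 for NDUFA4L2, 1.23 for BIRC3, -4.24 for CLDND1, 0.53 for SLC16A3, 1.45 for SLC7A2, 0.82 for PFKFB4, 2.26 for GJB1 and 1.64 for CRYBG1. Genes called in opposite directions with the siRNAs were PRSS8 (2.59), PNMA1 (0.92), RPS28 (-1.55), LAMA3 (1.33), ACTA2 (-2.79), HRNR (5.95), GPER1 (3.94), SUSD2 (3.46), CRIPAK (-3.19) and MFSD3 (-2.40). The remaining differences were SELENON (3.72), PLA2G7 (3.37), TNFRSF10D (-3.28) and SIPA1L2 (-2.39).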

How the results depend on the processing

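All settings were planned except 3: the count of lists called in the same direction with each siRNA, the genes without hexamers and a scaling without mitochondrial and ribosomal RNA genes (RHOB 1.19), which were chosen after seeing the data. Genes called in the same direction with both siRNAs numbered 2923 with DESeq2 size factors, 2929 with total counts, 2816 and 2917 with other filters, 2675 with the DESeq2 Wald test, 2972 with limma-voom and 3060 with only the groups compared, a setting not applicable to the mean contrast. Of the 2916 genes, 2904, 2684, 2697, 2904, 2672, 2850 and 2820 were shared. With total counts the balance moved: 2692 of 6218 genes called with siSETDB1-2 were higher (43.3%, against 52.1%) and 1270 of 2929 with both, against 1502 of 2916. At least 2-fold, counts were 1513 (siSETDB1-1), 796 (siSETDB1-2), 776 (mean), 1586 (between siRNAs) and 277 (both), fewer by construction, as were the 948 genes without hexamers. Lists called numbered 8 with an estimated correlation, 7 with siSETDB1-2 alone and 4 in the same direction with each siRNA, against 15; the correlation between siRNAs was 0.350 at a mean log2 CPM of at least 2, and the cause was not tested. With each library left out, counts ranged over 6865 to 7461, 5422 to 6675, 5734 to 6897, 6890 to 7542 and 2548 to 3035, lists over 13 to 16, the correlation over 0.385 to 0.473, SETDB1 over -3.02 to -2.89 and RHOB over 1.19 to 1.24. The correlation was 0.460 to 0.473 without a control library and 0.385 to 0.408 without a siSETDB1-1 or siSETDB1-2 library. The cause of this difference was not tested. Of the named genes, RGS5, not called (0.0051), reversed with total counts (-0.031), limma-voom (-0.085) and the replicate block (-0.030), and ranged over -0.22 to 0.21 with a library left out; the cause was not tested. With siSETDB1-2 alone, where none was called, the direction of the list test reversed for epithelial (median 0.034), p53 (-0.046) and ribosomal protein genes (0.0010, a median still above 0), as medians of log2 CPM values; the cause was not tested. Calls were lost in some setting by 5 genes and 12 lists and gained by 4 lists.

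Replicate numbers did not pair the libraries: deviations from the group means correlated by -0.059 to 0.0061 for the same number and -0.061 to 0.088 for others. With the number as a replicate block, counts were 7423, 6072, 6557, 7483 and 2863, 13 lists were called, the correlation was 0.410, SETDB1 -2.95 and RHOB 1.21; the mesenchymal (camera adjusted p = 0.0999) and stress response lists (0.0518) were not called.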

Other observations

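The hypoxia list and its test were chosen after the result had been seen, as were the genes of this paragraph outside the naming rule (LDHA, BNIP3, PDK1, SLC2A1 and BHLHE40). Genes induced by low oxygen, among them enzymes and transporters of glycolysis, were lower with both siRNAs. LDHA, which makes lactate, changed by -1.47 ± 0.034 with siSETDB1-1 and -1.32 ± 0.034 with siSETDB1-2, BNIP3, a mitophagy receptor, by -1.81 ± 0.050 and -1.42 ± 0.048, PDK1, which limits pyruvate oxidation, by -0.66 and -1.45, the glucose transporter SLC2A1 by -0.85 and -1.23, and the transcription factor BHLHE40 by -1.81 and -1.65. Of 57 tested genes of the list, 43 fell and 2 rose in the mean contrast (median -0.71), and 35 fell and 2 rose with both siRNAs.

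A hypothesis is that the hypoxia-inducible group as a whole was lower, rather than the few genes that prompted the list. Without the genes seen first, 30 of 44 fell and 2 rose (median -0.58, camera p = 4.36e-10, and 0.000298 with an estimated correlation), which the hypothesis needed. The 44 still include SLC2A1, which was named above after its values had been seen. Between the siRNAs, 21 of all 57 tested members were higher with siSETDB1-2, 23 lower and 13 not called, so members differed both ways, and the test of the whole list (camera p = 0.711, and 0.662 with an estimated correlation) does not show that the siRNAs acted alike. A denser or less oxygenated state of the control cells, which both comparisons share, may give the same pattern as loss of SETDB1, and no value here separates the 2.

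By gene type, the genes called in the same direction with both siRNAs were 1387 higher and 1333 lower of 12019 protein-coding genes, 61 and 46 of 1328 other RNAs, 24 and 14 of 479 pseudogenes, and 30 and 21 of 399 genes not in GENCODE 29.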
